A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

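The samples were 4 two-colour DNA microarrays of Saccharomyces cerevisiae lacking RLM1. RLM1 encodes the transcription factor at the end of the cell wall integrity pathway, a kinase cascade whose last kinase is Slt2. Each array compared total RNA of a culture given zymolyase with RNA of the untreated part of the same culture. Zymolyase is an enzyme preparation that digests the glucan of the yeast cell wall. Per the labels' protocols, cells were grown in rich medium at 24 °C, zymolyase was added at 5 units per ml, cells were taken at 3 hours, and RNA was labelled with Cy5 or Cy3 during first-strand cDNA synthesis. The series' design text gives 2 cultures, each hybridised on 2 arrays with the dyes exchanged. Zymolyase RNA carried Cy3 on arrays 1 and 3 and Cy5 on arrays 2 and 4.

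The deposited values are 1 log ratio of the array's channels per feature. The scanner, the background correction, the normalization, the rule by which values were left blank and the log base are not given in the sources used here. The authors' deposited values were taken as log2 ratios, the usual base, so every fold given depends on that. The mean of each column lay between 0.0046 and 0.012 and its median between -0.070 and 0.017, so the arrays arrived centred, and the main setting used them as deposited. No intensities were analysed here, so signal over background is unknown and the number of arrays limits the precision.

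The deposited ratios were taken as not turned for the dye exchange: the genes with the largest values had opposite signs on arrays of opposite dye orientation. Arrays 2 and 4 were therefore multiplied by -1. This rests on the genes with the largest values; the correlations between arrays over all genes do not settle it. If the deposited ratios had already been turned, the genes called here would be dye differences. Which channel is the numerator is stated in no source used here. The ratio was read as Cy3 over Cy5. This reading is likely rather than settled. Its basis is that it puts the osmotic and general stress genes on the zymolyase side, and zymolyase is known to activate the Hog1 osmotic stress kinase in wild-type yeast. If the ratio is Cy5 over Cy3, every gene called higher was lower and every gene called lower was higher. The direction of the stress lists is for the same reason no independent evidence.

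The table held 6209 features. The 2 control features were left out. Of the rest, 5711 matched a gene of the R64 reference gene table, 57 of them by an older name, and 496 did not and kept the name of their reading frame. The reference served for names only. Features of reading frames that now belong to 1 gene were averaged (34 genes). This left 6172 genes and unmatched features, both counted as genes here. Of these, 4730 had a value on all 4 arrays and were tested, 985 had a value on some arrays and 457 on none.

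Changes were tested with limma 3.58.1 in R 4.3.3. The 2 arrays of a culture were averaged, so that dye effects cancel and n = 2 cultures, and the culture means were tested against 0 with lmFit and eBayes. The labels do not say which arrays share a culture. With 1 array of each orientation per culture there are 2 possible pairings, arrays 1 with 2 and 3 with 4, or 1 with 4 and 2 with 3. Both were fitted, and a gene counted as changed only if its Benjamini-Hochberg adjusted p was under 0.05 in both; the larger adjusted p is given throughout. With 1 residual degree of freedom per gene, limma estimated an infinite prior in both fits. Every gene therefore received the same standard error, 0.16 in the fit with the larger one, and the test amounted to a minimum size of 0.51 on the log2 scale. It takes no account of genes whose own values vary more than others. The SD given beside a mean is over the 4 arrays, which hold 2 cultures, and mixes dye, technical and culture differences.

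A total of 28 gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists, in both pairings. The lists were osmotic stress targets, general stress response, cell wall stress response, Rlm1-linked targets, cell wall mannoproteins, glucan synthesis and remodelling, chitin synthesis, cell wall integrity signalling, high osmolarity glycerol pathway components, heat shock factor targets, mating pheromone response, calcineurin targets, ribosome biogenesis, cytosolic ribosomal proteins, glycolysis, hexose transport, citric acid cycle and respiratory chain, amino acid synthesis, sulfur assimilation, phosphate starvation, iron regulon, ergosterol synthesis, proteasome, G1/S, G2/M, daughter cell separation, histones, and meiosis and spore formation. Camera with an estimated correlation and fry, a rotation test of a list by itself, were alternatives. Standard errors of list medians are bootstrap values over the members (2000 draws).

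Means and list medians given without an array are plain means of the other 3 arrays, unless said to be weighted by culture, as in the tests without that array, where the array left alone in a culture weighs more and the result is averaged over both pairings. The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. Named were the 12 genes with the largest mean in each direction that passed the test with the same sign on all 4 arrays, the 4 members of each list with the largest absolute mean, and RLM1 and SLT2. Features without a standard gene name, or of a dubious reading frame, were not eligible. Any other gene named in the text was chosen after its values were seen. The values of 1 gene are not reported here. Alternatives were each pairing alone, 4 arrays as independent replicates, a dye term, the culture as a random block, median centring, scaling to 1 median absolute deviation, single features, a looser rule for missing values, a robust prior, a minimum change of 2-fold, and leaving out each array. On simulated data with the dye effect and array spread of these arrays (4730 genes, 200 of them changed, 20 runs), the test recovered 55.4% of changes of 0.5, 99.9% of changes of 1 and 100% of changes of 2 on the log2 scale, with 3.4% of its calls false. These shares hold for the simulated values only. The simulation gave all genes the same spread on an array, gave array 4 the spread of arrays 1 and 3, and held no difference between cultures. The shared standard error was therefore right by construction. The contrasts between the cultures on the real arrays had more genes of the called size than 3.4% of the calls.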

Results

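The response of yeast to 3 hours of wall digestion by zymolyase was measured in a strain without RLM1. This asks which genes change with the wall stress when the transcription factor of the cell wall integrity pathway is missing. The 4 arrays held values for 5545, 4815, 5659 and 5552 features (arrays 1 to 4). Array 2 had 1394 features without a value and the widest log2 ratios, with an SD of 0.63 over features against 0.32 to 0.35 on the other arrays. RLM1 had no value on any of the 4 arrays, so the ratios neither show nor exclude its absence. SLT2, the kinase upstream of Rlm1, had a mean log2 ratio of 0.00 ± 0.46 (SD, n = 4 arrays) and did not pass the test (adjusted p = 1.00). Which dye is the numerator of the deposited ratio is not stated. All signs, and the words rose and fell, rest on reading it as Cy3 over Cy5, a likely reading taken from the side on which known stress genes lie; the opposite reading turns each of them.

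With arrays 2 and 4 turned for the dye exchange, 149 of 4730 genes passed the test with zymolyase, of which 111 rose and 38 fell. These calls include 7 features with no reference gene, which may repeat a neighbouring gene. Taking the deposited ratios as already turned, an alternative chosen after the data were seen, gave 215 higher and 101 lower, of which 3 and 2 were shared. Among the genes tested, the small heat shock protein gene HSP12, a membrane protein of many stresses, rose most. Its log2 ratio was 2.75 ± 0.49 (SD, n = 4 arrays), which is 6.72-fold. RTC3 followed at 2.73 ± 0.89, and the low-affinity glucose transporter gene HXT1 at 2.12 ± 0.47. GPD1, which encodes the glycerol-3-phosphate dehydrogenase of glycerol synthesis, rose 3.59-fold. Of the genes that rose, 22 did so by 2-fold or more. The decreases were smaller: only the wall mannoprotein gene TIR3 fell by more than 2-fold, with a log2 ratio of -1.17 ± 0.63.

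**Figure D1:**
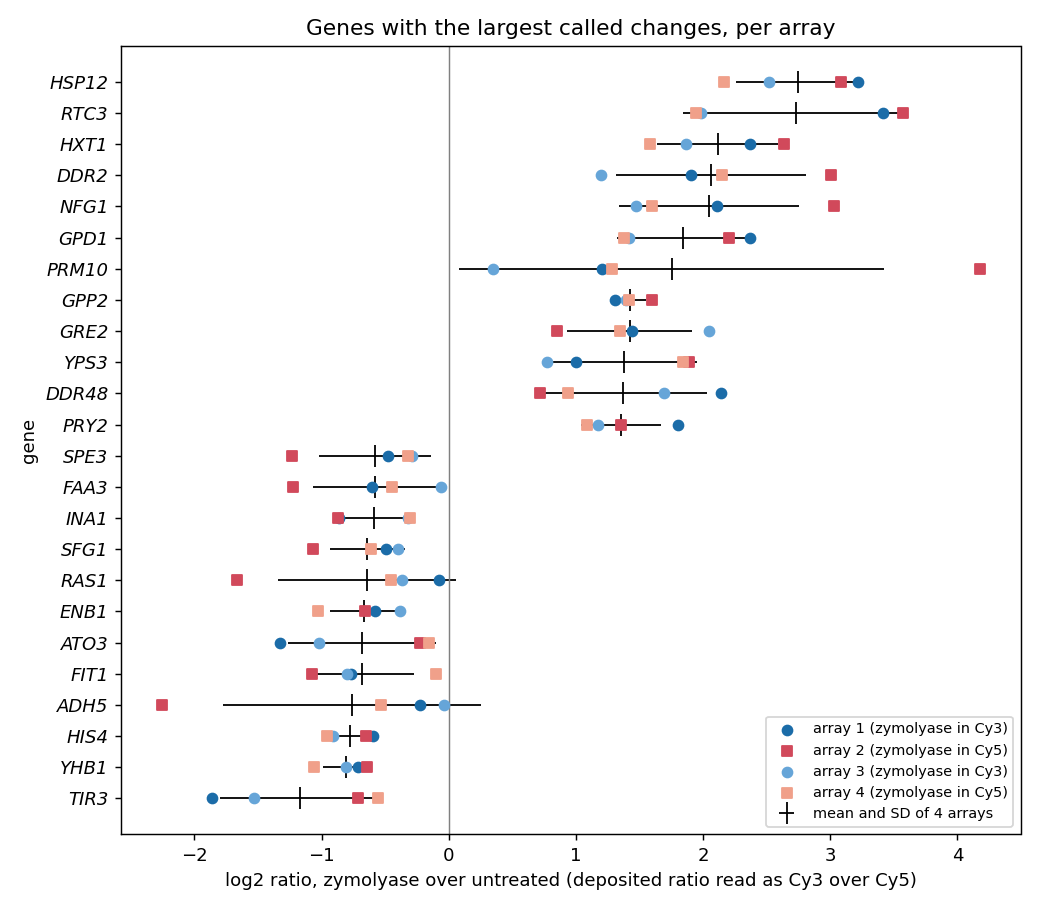
Log2 ratio of zymolyase over untreated (x axis, deposited ratio read as Cy3 over Cy5) for the 12 genes with the largest increases and the 12 with the largest decreases among genes with a standard name that passed the test with 1 sign on all 4 arrays (y axis). Points are single arrays, circles with zymolyase RNA in Cy3 and squares with it in Cy5; ticks and bars are the mean and SD of 4 arrays. GPP2 lies between 1.31 and 1.60 on all arrays, whereas PRM10 ranges from 0.35 to 4.18.

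Among genes with a standard name and 1 sign on all 4 arrays, the 12 largest increases also held DDR2 (2.06 ± 0.75), NFG1 (2.05 ± 0.71), PRM10 (1.75 ± 1.67), GPP2 (1.43 ± 0.12), GRE2 (1.42 ± 0.49), YPS3 (1.38 ± 0.58), DDR48 (1.37 ± 0.66) and PRY2 (1.35 ± 0.32), each as mean log2 ratio with SD over 4 arrays. GPP2 encodes the phosphatase that completes glycerol synthesis after Gpd1, and YPS3 a wall-anchored aspartic protease. Their adjusted p values in limma lay between 5.0e-59 for HSP12 and 2.7e-14 for PRY2. As all genes share 1 standard error from 2 cultures, these values only restate the size of the means. In the limma fit with a dye term the adjusted p values of the 12 ran from 2.2e-05 for HSP12 to 0.022 for PRM10. The mean of PRM10 was carried by array 2, at 4.18, against 0.35 to 1.29 on the others, and the mean of the others was 0.95. HXT1 belongs to a family of very similar transporter genes, and its value is uncertain where relatives share its spot.

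Among the decreases, the flavohemoglobin gene YHB1, which detoxifies nitric oxide, had a log2 ratio of -0.81 ± 0.18 and the histidine synthesis gene HIS4 of -0.78 ± 0.18. YHB1 lay between -1.06 and -0.64 on the 4 arrays and HIS4 between -0.96 and -0.60. ADH5 (-0.76 ± 1.02), FIT1 (-0.68 ± 0.41), ATO3 (-0.68 ± 0.58), ENB1 (-0.66 ± 0.27), RAS1 (-0.64 ± 0.70), SFG1 (-0.64 ± 0.30), INA1 (-0.59 ± 0.32), FAA3 (-0.58 ± 0.49) and SPE3 (-0.58 ± 0.44) made up the rest of the 12. FIT1 and ENB1 serve the uptake of iron bound to siderophores. ADH5 fell on every array but was -2.26 on array 2 and -0.04 on array 3. The adjusted p values of these 12 ran from 1.7e-10 for TIR3 to 0.016 for SPE3. With a dye term 6 of them did not pass: ADH5 (adjusted p = 0.15), FIT1 (0.068), RAS1 (0.14), INA1 (0.097), FAA3 (0.13) and SPE3 (0.13). Over arrays 1, 3 and 4 the means were -0.27 for ADH5, -0.30 for RAS1, -0.37 for FAA3 and -0.36 for SPE3. That of ATO3 over arrays 2, 3 and 4 was -0.47, or -0.40 with the arrays weighted by culture.

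The same sign on all 4 arrays was found for 97 of the 111 genes that rose and 26 of the 38 that fell, which selection on the mean by itself favours. Contrasts between the cultures, which hold no treatment effect, passed the size of the smallest call in 32 genes under one pairing (11 above, 21 below) and 23 under the other (22 above, 1 below). Set against 149 calls this is a larger share than the 3.4% of false calls on simulated data. A dye term fitted to all 4 arrays kept 68 of the increases and 9 of the decreases. That fit counts the 4 arrays as independent, although they hold 2 cultures. With 1 array left out the dye effect no longer cancels: 18 genes rose and 2 fell without array 1, 23 and 0 without array 2, 17 and 3 without array 3, and 8 and 0 without array 4. Past the test whichever array was left out, and with the dye term, were HSP12, RTC3, HXT1, DDR2, NFG1, GPD1 and YDL023C, a reading frame numbered next to GPD1 that was outside the naming rule. Genes with the largest values decided the turning of arrays 2 and 4. The agreement of such genes over the turned arrays is thus partly built in and is no independent evidence for the turning.

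**Figure D2:**
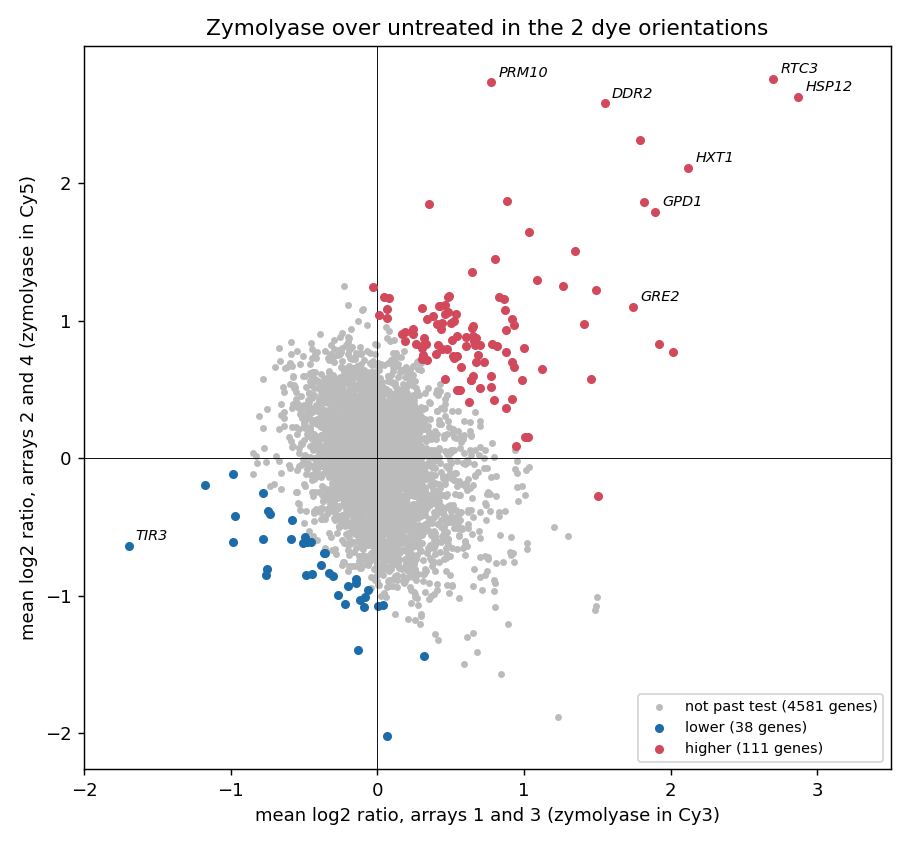
Mean log2 ratio of zymolyase over untreated on arrays 1 and 3, with zymolyase RNA in Cy3 (x axis), against the mean on arrays 2 and 4, with it in Cy5 (y axis); each point is 1 of 4730 genes, coloured by the test, and the deposited ratio is read as Cy3 over Cy5. The 111 genes called higher were selected on the mean of both axes and lie mostly in the upper right. Over all genes, called or not, the means on the 2 axes correlated at Pearson r = -0.081 and Spearman r = -0.22.

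Genes differed between the dye orientations by a spread at least as wide as that of the treatment means. After turning, arrays of the same orientation correlated across genes at r = 0.60 (arrays 1 and 3) and 0.44 (arrays 2 and 4), whereas arrays of opposite orientation correlated between -0.13 and 0.051. Spearman correlations of the opposite pairs were all negative, between -0.21 and -0.095. Genes are not independent replicates, so no test goes with these values. The contrast between orientations passed the size of the smallest call in 158 genes above and 74 below, more than the 111 and 38 calls, though an equal dye effect cancels in the means tested. It had an SD of 0.26 over genes, the treatment mean 0.24, and the contrasts between cultures 0.15 and 0.16. The median absolute deviation, which a few large values move less, was 0.25 for the orientation contrast and 0.18 for the treatment mean. For the contrasts between cultures it was 0.14 and 0.15.

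Osmotic stress targets are genes that the Hog1 kinase raises in osmotic stress. Of 16 measured, 10 rose, none fell and 6 did not pass; adjusted over the list alone 12 rose. Besides HSP12, RTC3, GPD1, GPP2 and GRE2 these were ALD3 (1.34 ± 0.41), MSC1 (1.01 ± 0.18), DAK1 (0.81 ± 0.05), GPP1 (0.72 ± 0.17) and GRE3 (0.58 ± 0.25), the last not past the test with a dye term (adjusted p = 0.055). The list's median log2 ratio was 0.76 (bootstrap SE 0.30), between 0.73 and 0.91 on single arrays (camera adjusted p = 3.6e-50; with an estimated correlation, adjusted p = 0.45). The Hog1 pathway's own components did not move as a list: none of 18 passed, or 1 rose adjusted over the list alone (median 0.03, adjusted p = 0.79), and MSB2, a sensor of the pathway, had the largest mean at 0.49 ± 0.27 (adjusted p = 0.072).

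General stress genes, which depend on the transcription factors Msn2 and Msn4, rose in 14 of 34 measured, none fell and 20 did not pass; over the list alone 20 rose and 1 fell. Members that rose and that the osmotic list does not hold included DDR2, DDR48, the wall protein gene SPI1 (1.26 ± 0.28), SOL4 (1.13 ± 0.46) and TSL1 of trehalose synthesis (0.91 ± 0.05). The median was 0.39 (bootstrap SE 0.11; camera adjusted p = 1.8e-29, with an estimated correlation adjusted p = 0.45). Because these stress lists are the basis for reading the ratio's direction, their direction is not independent evidence. Of 24 chaperone genes under the heat shock factor Hsf1 none passed (over the list alone 1 fell), and 22 had a negative mean. The median was -0.21 (camera adjusted p = 0.00016, with an estimated correlation adjusted p = 0.45, and 0.13 without array 2). The medians of that list were -0.03 and 0.01 with zymolyase in Cy3 on arrays 1 and 3, and -0.53 and -0.29 on arrays 2 and 4. STI1 (-0.51 ± 0.49, adjusted p = 0.055), SSA4 (-0.45 ± 0.73), HSP82 (-0.42 ± 0.87) and FES1 (-0.40 ± 0.57) had its largest means. Over arrays 1, 3 and 4 the list median was -0.13 and these genes stood at -0.27, -0.087, -0.085 and -0.15; HSP82 turned to 0.011 with the arrays weighted by culture.

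**Figure D3:**
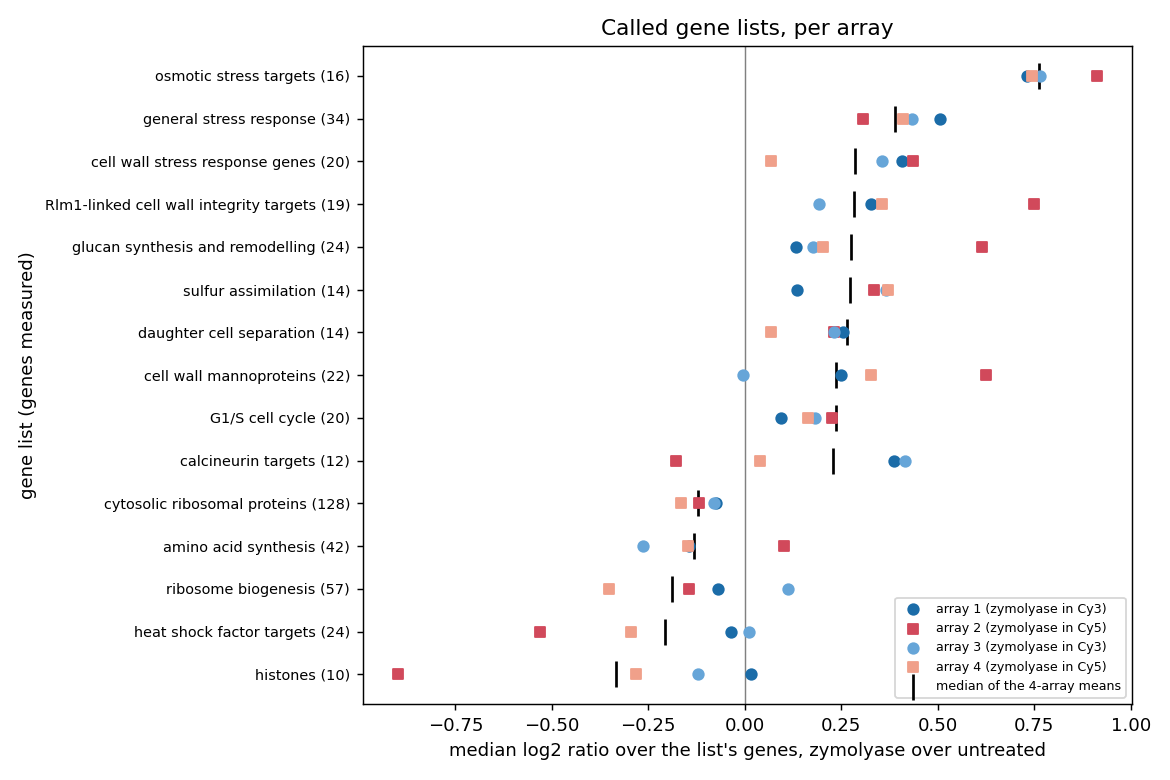
Median log2 ratio of zymolyase over untreated (x axis, deposited ratio read as Cy3 over Cy5) for the 15 gene lists past the camera test (y axis, genes measured in brackets). Points are single arrays, circles with zymolyase RNA in Cy3 and squares with it in Cy5, and the tick is the median of the genes' 4-array means. The osmotic stress list lies at 0.73 or more on all arrays; the ribosome biogenesis, heat shock, histone, amino acid, calcineurin and mannoprotein lists have arrays on both sides of 0.

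Some cell wall genes rose in this strain without RLM1. Of 19 measured genes tied to Rlm1 in wild-type cells, 5 rose, none fell and 14 did not pass; over the list alone 7 rose. The 5 encode wall proteins or wall enzymes: SED1 (0.81 ± 0.19), CIS3 (0.79 ± 0.39), CWP1 (0.77 ± 0.26), the chitin-glucan crosslinking enzyme gene CRH1 (0.71 ± 0.41) and HSP150 (0.61 ± 0.13). SLT2 did not pass, nor did PST1 (adjusted p = 0.84) and PIR3 (0.98), of which the last pair was singled out after its values were seen. The median was 0.28 (bootstrap SE 0.09; camera adjusted p = 2.6e-07, with an estimated correlation adjusted p = 0.45). Without array 2 the median was 0.22 (bootstrap SE 0.11).

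The wider wall stress list, which shares members with the preceding one, had 7 of 20 genes up, 1 down (FIT1) and 12 that did not pass; over the list alone 8 rose and 2 fell. HSP12, PRM10 and YPS3 led it (median 0.29, or 0.15 without array 1; camera adjusted p = 6.2e-14, with an estimated correlation adjusted p = 0.45). HSP12 is also an osmotic stress target, so the direction of the wall stress list is not fully independent of the reading of the ratio. The mean of PRM10 without array 2 was 0.95. Among 22 wall mannoproteins 6 rose, TIR3 fell and 15 did not pass; over the list alone 9 rose and 1 fell (median 0.24, or 0.41 without array 3; camera adjusted p = 2.8e-05, with an estimated correlation adjusted p = 0.45). In glucan synthesis and remodelling 5 of 24 rose, none fell and 19 did not pass, and 7 rose and 1 fell over the list alone. They were CRH1, the glucan synthesis gene KRE6 (0.63 ± 0.21), DSE2 (0.60 ± 0.40), GAS2 (0.59 ± 0.61) and EXG1 (0.53 ± 0.30). With a dye term DSE2 (adjusted p = 0.064), GAS2 (0.15) and EXG1 (0.13) did not pass. Over arrays 1, 3 and 4 the mean of DSE2 was 0.42, or 0.39 with the arrays weighted by culture. The mean of GAS2 over the same arrays was 0.31, and GAS2 was -0.0092 on array 3. That list's median was 0.28 (camera adjusted p = 3.1e-05, with an estimated correlation adjusted p = 0.66), and 0.16 without array 2, where it was 0.61. Chitin synthesis (0 of 10 past the test) and the sensors and kinases of the cell wall integrity pathway (0 of 17) did not pass as lists (adjusted p = 0.79 and 0.80). GFA1, the first enzyme of chitin precursor synthesis, had a mean of 0.41 ± 0.50 (adjusted p = 0.19), and 0.18 without array 2. GSC2, a glucan synthase gene that calcineurin raises, ranged from -1.04 on array 2 to 1.57 on array 1.

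Genes of protein synthesis showed small shifts without any single call. Of 128 cytosolic ribosomal protein genes 120 had a negative mean and none passed, over the list alone too; the median was -0.12 (bootstrap SE 0.013; camera adjusted p = 2.1e-06, with an estimated correlation adjusted p = 0.45). Many of these genes are near-identical pairs whose spots share labelled cDNA. RPL39 (-0.50 ± 0.72) and RPS30B (-0.45 ± 1.22) had the largest means, which without array 2 were -0.14 and -0.11. With the arrays weighted by culture RPS30B turned to 0.066 without array 2 and 0.072 without array 4. Ribosome biogenesis genes had a negative mean in 49 of 57, with none past the test and a median of -0.19 (camera adjusted p = 9.5e-05, with an estimated correlation adjusted p = 0.50). Their median was 0.02 with zymolyase in Cy3 and -0.32 with it in Cy5, and the list did not pass without array 2 (adjusted p = 0.18) or without array 4 (0.27). That median was -0.090 without array 2 and -0.095 without array 4. CBF5 (-0.48 ± 0.95) had its largest mean, at -0.039 without array 2. Histone genes (0 of 10 past the test, median -0.33, camera adjusted p = 0.0029, with an estimated correlation adjusted p = 0.47) did not pass without array 2 (adjusted p = 0.17, median -0.13). Their median was -0.054 with zymolyase in Cy3 and -0.62 with it in Cy5.

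Sulfur assimilation genes, which make methionine and cysteine from sulfate, rose in 3 of 14 (MET28 at 0.83 ± 0.49, MET14 at 0.67 ± 0.64 and MET10 at 0.62 ± 0.51), 11 did not pass, and 13 had a positive mean (median 0.27, camera adjusted p = 1.7e-05, with an estimated correlation adjusted p = 0.45). Amino acid synthesis genes under Gcn4 went both ways. Of 42 measured, 4 fell, among them HIS4, ARG1 (-0.57 ± 1.10) and ARG4 (-0.56 ± 0.58), MET6 (0.61 ± 0.33) rose and 37 did not pass (median -0.13, camera adjusted p = 0.0024, with an estimated correlation adjusted p = 0.69). ARG1 was positive on arrays 1 and 2 and at -1.83 and -1.15 on arrays 3 and 4. With a dye term MET14 (adjusted p = 0.15), MET10 (0.14), ARG1 (0.48), ARG4 (0.14) and MET6 (0.084) did not pass. With 1 array left out the mean of the other 3 was -0.88, -0.87, -0.15 and -0.38 for ARG1 (without arrays 1 to 4), -0.37 for ARG4 without array 4 and 0.41 for MET10 without array 2. The amino acid list did not pass without array 1 (adjusted p = 0.16) or array 3 (0.49, median -0.061). Over each list alone, 3 sulfur genes rose, and 1 amino acid gene rose and 6 fell.

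Of 20 genes of the G1/S transition, 2 rose and 18 did not pass, or 4 rose over the list alone (median 0.24, or 0.14 without array 2; camera adjusted p = 0.00023, with an estimated correlation adjusted p = 0.45). They were GIC2 (0.77 ± 0.52), an effector of Cdc42 in bud emergence, and the G1 cyclin gene PCL2 (0.72 ± 0.38). Without array 2 the mean of GIC2 was 0.52, or 0.49 with the arrays weighted by culture, and that of PCL2 was 0.53. Genes of daughter cell separation had 1 of 14 up, DSE2, and 5 over the list alone (camera adjusted p = 0.0098, with an estimated correlation adjusted p = 0.50); that list did not pass without array 1 (adjusted p = 0.21) or array 3 (0.24). Calcineurin targets had 1 of 12 up, the protease gene YPS1 (0.52 ± 0.13; adjusted p = 0.087 with a dye term), and 2 over the list alone (camera adjusted p = 0.020, with an estimated correlation adjusted p = 0.55), and did not pass without array 1 (adjusted p = 0.78) or array 3 (0.73). The calcineurin median was 0.23, and 0.081 without array 1 and 0.11 without array 3. The G2/M list (0 of 13 past the test, adjusted p = 0.70), mating pheromone response (0 of 20, 0.79), proteasome (0 of 33, 0.47), ergosterol synthesis (0 of 23, 0.91), phosphate starvation (0 of 14, or 1 lower over the list alone, 0.41) and glycolysis (0 of 17, 0.17) did not pass as lists. Meiosis and spore formation, a list of another cell state, had 1 of 8 measured genes past the test, GAS2, and did not pass as a list (adjusted p = 0.79). It passed without array 2 (adjusted p = 0.0075, on more measured genes), where the median of the 8 genes was -0.25. Their median was -0.37 with zymolyase in Cy3 and 0.32 with it in Cy5.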

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

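Most tests in this part were chosen after the arrays had been seen. Set down before their values were known were the list medians and camera without array 2, and camera with an estimated correlation. The fit without array 2 and with a dye term was chosen afterwards. A total of 148 measures were compared over the 4 arrays and 12 had 1 array far from the other 3; chance flags about 1 in 20, so most of the genes and lists named here may be chance, and only the flags of array 2 as a whole were followed up (without array 2 and with a dye term, 7 genes rose and 0 fell).

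Array 2 stood apart in features without a value (1394, against 550 to 664), in the SD of the deposited ratios (0.63, against 0.32 to 0.35) and in their median absolute deviation over tested genes (0.62, against 0.24 to 0.26). It also stood apart for KRE6 (0.95 against 0.48 to 0.55), CHS3 (-0.87 against -0.07 to 0.03), RPS29B (-1.08 against -0.25 to -0.16) and the median of the glucan list (0.61 against 0.13 to 0.20). Array 1 stood apart for YPS1 (0.32 against 0.56 to 0.60) and for the sulfur assimilation median (0.14 against 0.34 to 0.37), array 4 for BRX1 (-1.51 against -0.20 to -0.01) and the daughter cell separation median (0.069 against 0.23 to 0.26), and array 3 for the G2/M median (0.24 against -0.10 to -0.06).

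The genes called higher and lower differ in how far they exceed the spread between arrays. The larger side of the contrasts between cultures, which hold no treatment effect, had 22 genes beyond the size of the smallest call. This is fewer than the 111 increases but of the same order as the 38 decreases, so a large part of the decreases may be spread. The size of the smallest call was set from these same contrasts, as the pooled standard error equals their SD (0.15 and 0.16). An excess of calls over contrast genes is thus largely built in and is no independent evidence against spread. Of the increases, 18 lay beyond the largest absolute culture contrast of 1.17, and of the decreases none did. The contrast between dye orientations had 158 genes above and 74 below that size, so the counts speak of spread between cultures only, and rest on the turning of arrays 2 and 4.

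The osmotic stress median was 0.72 without array 2, more than 2 bootstrap SE above 0. Single arrays 1, 3 and 4 gave 0.73, 0.76 and 0.75, which argues against array 2 as the cause. A dye effect of equal size cancels in the list's 4-array median of 0.76 (bootstrap SE 0.30) with the turning as taken. The 0.73 in the weaker orientation is no test of that turning, which genes of this list helped to decide. The Rlm1-linked median was 0.30 (bootstrap SE 0.15) in its weaker orientation, just over 2 SE, with the turning as taken. It was 0.22 (bootstrap SE 0.11) without array 2, just under 2 SE, so a contribution of array 2 stays open. Camera still called the list without array 2 (adjusted p = 1.9e-06 at the preset correlation). On all 4 arrays camera gave adjusted p = 0.45 with an estimated correlation. The ribosomal protein median was -0.070 (bootstrap SE 0.015) in its weaker orientation, more than 2 SE below 0 with the turning as taken. With the turning as taken, a dye effect alone would give the Rlm1-linked and ribosomal protein lists opposite signs in the 2 orientations, which was not seen. Had the deposited ratios already been turned, a dye effect would give the same sign in both. The signs therefore cannot exclude a dye effect while the turning is open. Their SE are over the genes of a list on the same arrays, however, and hold no spread between arrays or cultures. Passing 2 SE therefore does not settle a dye effect or the part of array 2. With the turning as taken, a dye effect of equal size cancels in the ribosome biogenesis median over 4 arrays, which was -0.19 (bootstrap SE 0.036). The 0.020 over arrays 1 and 3 leaves a shift on arrays 2 and 4 alone open. By the labels every array was of a strain lacking RLM1. Any real response of the osmotic and Rlm1-linked lists on these arrays therefore occurred without Rlm1. Whether Rlm1 would alter such a response was not tested, as no strain with RLM1 was analysed here.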

How the results depend on the processing

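The alternatives were fixed beforehand, except the other reading of the ratio, the ratios taken as already turned, the dye term with an estimated correlation, the demand for 1 sign on all arrays, the fit without array 2 and the array weights, which were chosen after seeing the data. Counts of genes higher and lower stayed within 1.5 times of 111 and 38 under each pairing alone, median centring, single features, the looser rule for missing values, the robust prior and 1 sign on all arrays. They moved to 17 and 0 with 4 arrays as independent replicates, 68 and 9 with a dye term, 59 and 8 with the culture as a random block, 21 and 1 by 2-fold size with 1 sign on all arrays, 22 and 1 with the test and 2-fold, 65 and 9 with array weights and a dye term, and 7 and 0 with arrays 1, 3 and 4 and a dye term; scaling to 1 median absolute deviation gave 89 and 18. All 68, 9, 59, 8 and 17 genes of the 4-array fits were among the main calls. The 4-array fit without a dye term counts the dye effect as error, and size rules call fewer genes by construction. For the others the cause was not tested. With the culture as a random block, the estimated correlation between arrays of a culture was negative, -0.45 and -0.39 for the 2 pairings. That fit therefore did not treat the arrays of a culture, which carry opposite dyes, as alike. The array weights came out equal within each orientation, so they do not weigh array 2 against array 4. Leaving out 1 array gave 8 to 23 genes higher and 0 to 3 lower. Reading the ratio as Cy5 over Cy3 exchanges the counts, to 38 higher and 111 lower, and taking the ratios as already turned gives 215 and 101, of which 3 and 2 are shared. The 15 called lists became 16 with 4 independent arrays or a dye term, 12 to 14 with 1 array left out, and 0 with an estimated correlation, with fry, or with a dye term and an estimated correlation (smallest adjusted p 0.45, 0.16 and 0.17, with 1, 1 and 2 residual degrees of freedom; 1 list, general stress, had an unadjusted p under 0.05 with an estimated correlation). No named gene changed sign past the test under any alternative run on named genes, and median centring and scaling turned the sign of no called list's median.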

Other observations

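The comparison of neighbouring features was set down before its result was seen; every gene named here that is not a list member was chosen after its values were seen. With the ratio read as Cy3 over Cy5, several genes of the vacuole rose: the protease gene PRB1 (0.77 ± 0.34), its inhibitor gene PBI2 (0.96 ± 0.22) and the mannosidase gene AMS1 (0.79 ± 0.45), as mean log2 ratio with SD over 4 arrays and the same sign on each. The aldehyde dehydrogenase genes ALD4 (1.02 ± 0.53) and ALD6 (0.97 ± 0.30) rose too, as did OCH1 (1.19 ± 0.37), which starts the outer mannose chain of N-glycans. No enrichment was tested for these genes. Zeo1, encoded by ZEO1, is a membrane-associated protein; its gene had the second lowest mean, -0.98 ± 1.30, but was 0.64 on array 1 and -2.23 on array 4.

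Iron uptake genes under Aft1 went both ways: ARN1 rose (0.68 ± 0.41), FIT1, ENB1 and FIT3 (-0.53 ± 0.53) fell (FIT1 and FIT3 not with a dye term, adjusted p = 0.068 and 0.28; the mean of FIT3 over arrays 1, 3 and 4 was -0.32) and 14 of 18 did not pass, and the list did not pass (adjusted p = 0.69); over the list alone 3 rose and 4 fell. In the hexose transport list HXT1 rose, HXT2, a transporter of low glucose, fell (-0.53 ± 0.21; adjusted p = 0.081 with a dye term) and 9 of 11 did not pass (list adjusted p = 0.20); over the list alone 2 rose and 2 fell. Of 44 genes of the citric acid cycle and respiratory chain, IDH2 (0.52 ± 0.57) rose, CYC1 (-0.52 ± 0.33) fell and 42 did not pass, also over the list alone (list adjusted p = 0.17). With a dye term neither IDH2 (adjusted p = 0.14) nor CYC1 (0.13) passed, and over arrays 2, 3 and 4 the mean of IDH2 was 0.26. The list itself passed camera with a dye term at the preset correlation (adjusted p = 0.048), but not with an estimated correlation (0.485). Among genes with a value on 3 arrays only, which were not tested, NQM1 stood at 3.09, 2.88 and 2.57, the catalase gene CTT1 at 0.82, 1.15 and 1.43, and YJL107C, numbered next to PRM10, at 0.94, 3.29 and 1.01.

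Features that match no reference gene tended to follow their neighbours. YDL023C (1.84) tracked GPD1 (1.84), and YMR173W-A (1.40) tracked DDR48 (1.37). Across 276 pairs of next-numbered features in which at least 1 had no reference gene, the mean log2 ratios correlated at r = 0.36, against 0.031 in 3340 pairs of reference genes, a difference of 0.33 (bootstrap SE 0.13). Without the 1 pair that holds GPD1, an exclusion added afterwards, the difference was 0.16 (bootstrap SE 0.057). The values are consistent with spots that take up labelled cDNA of an overlapping gene, and calls at such features may then repeat the neighbour's.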
